A study of Ovis aries with 15 samples.

How the data were processed

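Ruminal epithelium of male Hu lambs aged 6 months was sequenced as total RNA after Trizol extraction, per the labels' protocols, in 15 libraries of 3 groups (CON, HG and HP) with 5 libraries each. The authors deposited 1 table per library with FPKM values, which are fragments scaled by transcript length and by the mapped fragments of the library, per the file headers. HISAT2 and StringTie 1.3.4d are named in the submitters' processing notes with no role or order; the version of HISAT2, the genome build, the annotation, trimming and filters are not given in the sources used here. FPKM removes depth and assumes a gene length, so total reads per library are unknown, no counting interval can be given, and a few abundant genes can shift all other values of a library. Low values showed no steps of whole reads, so no counts were recovered. No count test was run, nor any scaling or filter that needs counts, and median-ratio scaling was applied to FPKM. An exact 0 can be a failed estimate: of 1251 genes with a mean of at least 50 FPKM, 0 to 3 were listed at 0 in each library.

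Each table held the same 19304 genes. A symbol was given for 13214, 4157 had none, and of 1933 entries named by a gene number, 320 took a symbol from the RefSeq table of assembly ARS-UI_Ramb_v3.0, which was used for names only. Of the list members, 4 were matched through an older symbol. Type I keratins and ribosomal proteins have close relatives or pseudogenes whose reads may be shared, and their values are uncertain.

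The main test was limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, robust with statmod 1.5.0) on log2(FPKM + 1), so that fold changes of low genes are understated. Genes with at least 1 FPKM in at least 5 libraries were kept, 13084 in all, of which 11222 had a symbol. All 15 libraries entered 1 model of group means with 3 contrasts, and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Before the data were examined, 32 gene lists were fixed, of which 25 had at least 5 members tested. The 7 others were mitochondrially encoded genes (0 tested), B and plasma cell (3), skeletal muscle (4), adipocyte (2), Schwann cell and neuron (2), melanocyte (1) and red blood cell (1). Lists were tested two-sided with camera at a preset correlation of 0.01, adjusted over 25 lists, and again with an estimated correlation, under which 0 of 25 lists were called in each contrast (smallest adjusted p 0.707, 0.53 and 0.78 for HG against CON, HP against CON and HP against HG). An exact permutation test of list scores per library, over 252 assignments, was added after seeing the data. With scores relative to all genes tested, 9, 6 and 0 lists had an unadjusted p under 0.05 and 0 passed adjustment in each contrast. Scores not taken relative to all genes hold the shift of all genes. With these, tight junction, basal keratinocyte, growth factor signalling and immediate early genes had an exact adjusted p of 0.0496 in HG against CON. No list passed in the other contrasts.

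Genes were named by a rule fixed before the data were examined. It took the genes past the threshold with a symbol and a mean of at least 5 FPKM in the higher group, up to 8 per direction. From each list tested it took the 4 members with the smallest p, and where a contrast had fewer than 10 calls, the 10 genes with a symbol, that mean and the smallest p. A gene named for one contrast could be given in the others. The rule gave 230 genes, and the text names only some of them.

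The gene test was tested on simulated data made from the real gene means and spreads. For 13084 genes with 100 changed 2-fold and 100 changed 4-fold, and whole libraries of residuals shuffled between groups, it recovered 69% and 96% of these in HG against CON, and 65% and 95% in HP against CON. Of the unchanged genes 3 and 4 were called. Changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, so recovery of lower genes is not known. The shuffle also spread CON1 and CON3 over the groups, while in the data both lie in CON. In a separate simulation with noise drawn independently for each gene, the tight junction list, moved by a known amount in HG, was recovered. In it 0 of the other lists were called. Members of the real lists move together (estimated correlation 0.375 for tight junction). This simulation therefore does not test the list calls at the preset correlation. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-ratio scaling, quantile normalization, fits of only the 10 libraries compared, array quality weights, the replicate number as a block, and each of the 15 libraries left out. Alternatives chosen after seeing the data left out CON1 with CON3 or CON2 with HP1, or used the smooth muscle score or the median-ratio factor as a covariate, or took TGM1 or SOD1 out of its list. The median-ratio factor differed between groups, at 0.916 ± 0.15 in CON, 1.06 ± 0.0388 in HG and 1.08 ± 0.0416 in HP (SD). As a covariate it can therefore take up a difference due to diet, and that fit cannot separate scaling from diet. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.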

Results

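The data were RNA-seq expression values from the ruminal epithelium, the stratified lining of the forestomach that absorbs the acids of fermentation, of male Hu lambs aged 6 months. The 15 libraries carried the labels CON, HG and HP, with 5 libraries in each group and 1 library per file. The title of the series names pelleted and non-pelleted high-grain diets, so HG was read here as the non-pelleted high-grain diet, HP as the pelleted one and CON as the control. Labels did not say outright that each library came from its own animal, so limma p-values and exact p-values of list scores measure the spread between these libraries. Camera p-values at the preset correlation do not: they set list members against other genes as if nearly independent. The estimated correlation of members was 0.479 for oxidative phosphorylation, 0.701 for ribosomal proteins and 0.775 for interferon-stimulated genes. Values were FPKM for 19304 genes, the depth of each library was unknown, and 13084 genes entered the tests. The median FPKM was 2.36 ± 0.602 in CON, 2.94 ± 0.21 in HG and 2.98 ± 0.201 in HP (SD, n = 5 each). Libraries CON1 and CON3 had the lowest medians, 1.98 and 1.52, and the ribosomal protein list took 15.9% and 17.3% of their FPKM against 10.2% to 14.1% in the other libraries. Over all genes tested, the median log2 fold change was 0.17 for HG against CON, 0.18 for HP against CON and 0.01 for HP against HG. Median-ratio scaling brought the first pair to -0.01 and -0.02. List differences below are therefore relative to the mean of all genes tested. Over all genes tested, 0 members of the 25 lists passed the threshold of limma in each comparison, and member counts are given adjusted over the list alone.

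**Figure D1:**
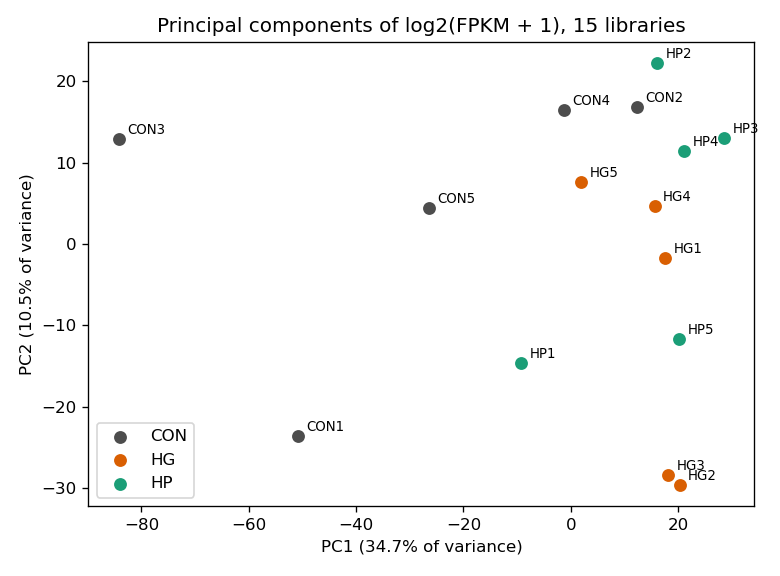
Principal components of log2(FPKM + 1) over the 13084 genes tested; each point is 1 library, coloured by group, with PC1 (34.7% of variance) on the x axis and PC2 (10.5%) on the y axis. CON3 and CON1 lie at -84.2 and -50.9 on PC1, and CON2 lies at 12.4 among the HG and HP libraries.

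The first comparison asked how the epithelium differed between the non-pelleted high-grain diet and the control. No single gene passed the threshold. By camera with a preset correlation, lists of the basal layer (0.35), cell junctions (0.25) and growth factor signalling (0.27) stood above CON relative to all genes. Oxidative phosphorylation (-0.50) and ribosomal proteins (-0.53) stood below it, at -0.20 and -0.15 without CON1 and CON3. With an estimated correlation 0 of 25 lists were called, with a smallest adjusted p of 0.707. COL17A1, a hemidesmosome collagen, was 88.3 ± 12.8 FPKM in HG and 52.4 ± 16.2 in CON, and the laminin chain gene LAMA3 was 14.2 ± 1.23 and 9.24 ± 2.54 (SD, n = 5 each). NDUFB5, a subunit of respiratory complex I, was 81.6 ± 8.02 in HG and 130.2 ± 29.3 in CON, below every CON library in 5 of 5 HG libraries. SLC9A3, a sodium/proton exchanger, was 48.5 ± 12.6 FPKM against 21.2 ± 14.9, and BDH1, an enzyme of ketone body formation, was 404.9 ± 97 against 226.3 ± 65.7. The ketogenesis list, which holds BDH1, was not called (-0.05, camera adjusted p 0.559). In it 7 of 14 members had a positive fold change, and 0 passed adjusted over the list alone.

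Among the 10 genes with the smallest p, ITPRIP came closest to the threshold, with 10.8 ± 1.04 FPKM in HG, 5.41 ± 1.25 in CON and a limma adjusted p of 0.0506. BCAR1, an adaptor protein of integrin signalling, was 24 ± 3.83 against 12.5 ± 1.32 FPKM, and LZTR1, a regulator of RAS proteins, was 8.97 ± 2.24 against 2.86 ± 1.08. The kinase gene MAP2K1 (MEK1) was 58.4 ± 19 against 23 ± 5.12. For the transcriptional regulators the values were 68.1 ± 11.1 against 27.5 ± 19.9 for PAX9, and 12.3 ± 3.32 against 4.52 ± 1.85 for MRTFA. CALCOCO1 was 20.2 ± 5.85 against 9.41 ± 2.33 and TUFT1 31.4 ± 4.13 against 20.2 ± 1.95. On the lower side, the splicing factor gene SF3B5 was 67.1 ± 8.93 in HG against 114.2 ± 25.2 in CON. CD5L, a protein secreted by macrophages, was 0.046, 0.643, 5.56, 2.47 and 0.111 FPKM in HG1 to HG5, against 5.46 to 40.9 in CON.

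By camera with a preset correlation, 5 of 25 lists were higher and 7 lower in HG than in CON. The basal keratinocyte list was higher by 0.35 log2 units relative to all genes (adjusted p 0.00827; p 0.105 with an estimated correlation), and 6 of its 16 members were higher adjusted over the list alone. Desmosome, adherens and gap junction genes were higher by 0.25 (adjusted p 0.0112; p 0.318 with an estimated correlation), 7 of 19 adjusted over the list alone. The difference was 0.40 under quantile normalization, 0.14 without CON1 and CON3 and 0.13 with the median-ratio factor as a covariate. Among the 7 were CTNND1 (98 ± 7.64 against 59.4 ± 22 FPKM), CDH1 (44.5 ± 4.59 against 29.1 ± 9.21) and JUP (193.1 ± 13.2 against 131.1 ± 26.1). Growth factor signalling was higher by 0.27 (adjusted p 0.0112; p 0.19 with an estimated correlation), 6 of 28 adjusted over the list alone. NOTCH3 was at 24.6 ± 2.75 against 11.9 ± 6.19 and the receptor gene ERBB2 at 25.2 ± 2.43 against 15.4 ± 3.59. IGF1R, the receptor of insulin-like growth factor, was 8.79 ± 0.924 against 4.54 ± 2.87. Tight junction genes were higher by 0.17 (adjusted p 0.0393; p 0.368 with an estimated correlation), 1 of 18 adjusted over the list alone. They lost their call under median-ratio scaling (0.14), with the median-ratio factor as a covariate (0.04), array quality weights (0.11), the smooth muscle covariate (0.16), without CON2 and HP1 (0.19) and without CON1 and CON3 (0.07). TJP3 was at 30.2 ± 4.58 against 20.6 ± 3.66 and CLDN1 at 106.6 ± 14.8 against 72.1 ± 20.2. Immediate early genes were higher by 0.43 (adjusted p 0.00902; p 0.229 with an estimated correlation), 6 of 18 adjusted over the list alone, and lost their call without CON2 and HP1 (0.31). EGR1 was at 8.78 ± 5.08 against 2.85 ± 1.6 and ATF3 at 4.59 ± 3.57 against 1.5 ± 0.681.

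Oxidative phosphorylation was lower by -0.50 relative to all genes (adjusted p 6.5e-15; p 0.0431 unadjusted and 0.707 adjusted with an estimated correlation), with 33 of 35 members below CON and 11 lower adjusted over the list alone. The difference was -0.20 under quantile normalization, -0.20 without CON1 and CON3 and -0.11 with the median-ratio factor as a covariate. Among the 11 was NDUFS4 (65.6 ± 8.02 against 111.6 ± 31.9 FPKM). Cytosolic ribosomal proteins were lower by -0.53 (adjusted p 6.5e-15; p 0.0934 unadjusted and 0.707 adjusted with an estimated correlation), a difference of -0.04 and no call under quantile normalization, of -0.03 and no call with the median-ratio factor as a covariate, and of -0.15 without CON1 and CON3, -0.33 without CON3 alone and -0.34 with array quality weights. In this list 38 of 39 members were below CON, 0 adjusted over the list alone by limma and 12 at an unadjusted p under 0.05. RPS23 was 731.6 ± 90.5 against 1261 ± 408 and RPL24 was 1378 ± 94.5 against 2161 ± 611.1, values that can include reads of ribosomal pseudogenes. Both lists were highest in CON1 and CON3. Cholesterol biosynthesis was lower by -0.23 (adjusted p 0.0298; p 0.285 with an estimated correlation), and lost its call under median-ratio scaling (-0.25), quantile normalization (-0.19) and the smooth muscle covariate (-0.17). Its members went both ways, 1 higher and 2 lower of 23 adjusted over the list alone. MSMO1 was 40.6 ± 11.7 against 74.7 ± 15.1, SC5D 5.03 ± 3.27 against 10.1 ± 1.15 and SQLE 14.8 ± 3.16 against 21.4 ± 5.15. The regulator gene SREBF2 was 95.1 ± 12.6 against 51.7 ± 21.8. The list of unfolded protein and heat shock response was lower by -0.21 (adjusted p 0.0081; p 0.145 with an estimated correlation; -0.03 and no call under quantile normalization, -0.105 with the median-ratio factor as a covariate), 2 of 27 adjusted over the list alone. The chaperone gene HSPD1 was at 117.2 ± 12.5 against 159.7 ± 17.6 and MANF at 80.8 ± 10.4 against 137.5 ± 42.3. The other lists called lower were cell cycle (-0.21), interferon-stimulated (-0.50) and antioxidant genes (-0.13), at unadjusted p of 0.424, 0.357 and 0.169 with an estimated correlation. Adjusted over the list alone, 0, 0 and 1 of their members were lower by limma, and 1, 0 and 4 at an unadjusted p under 0.05. Cell cycle genes lost their call with the smooth muscle covariate (-0.14) and without CON2 and HP1 (-0.19), and interferon-stimulated genes stood at -0.82 with the median-ratio factor as a covariate. Antioxidant genes stood at -0.20 with a pseudocount of 0.1 and without CON2 and HP1. They turned to 0.07 under quantile normalization and to 0.03 with no call with the median-ratio factor as a covariate, and lost their call under median-ratio scaling (-0.17), the stricter filter (-0.14) and without CON1 and CON3 (-0.01). In this list 15 of 26 members had a positive fold change before the shift of all genes was taken off.

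Not called as a list, transport of short-chain fatty acids, protons and bicarbonate had a difference of 0.20 (adjusted p 0.276) with 4 of 21 members higher adjusted over the list alone. Fatty acid oxidation stood at -0.01 (adjusted p 0.871), with 2 of 23 members higher and 1 lower adjusted over the list alone. At an unadjusted p under 0.05 by limma, 7 were higher and 3 lower. PPARA was at 6.94 ± 1.22 against 3.99 ± 1.25 and CPT1A, which carries long-chain fatty acids into mitochondria, at 12.7 ± 3.94 against 6.91 ± 2.26. The fibroblast list stood at 0.28 (adjusted p 0.0843), with 6 of 20 adjusted over the list alone and COL1A1 at 460.6 ± 136.2 against 245.1 ± 54.8. In the limma fit 0 genes were higher and 0 lower in HG than CON, with 2855 higher and 720 lower at an unadjusted p under 0.05. The latter were 1599 and 1675 under median-ratio scaling, 1518 and 1576 under quantile normalization, 1017 and 516 without CON1 and CON3, and 431 and 437 with the median-ratio factor as a covariate, where chance gives 654 in all. That factor was lower on average in CON, so the fit with it cannot separate scaling from diet. Without CON2, 1834 genes were higher and 384 lower, without HG3 3 and 1, without HP4 1 and 0, and array quality weights gave 656 and 212. Calls of lists were lost without CON2 (tight junction 0.19, immediate early 0.31), CON3 (tight junction 0.10), HG1 (interferon -0.19, cholesterol -0.19, tight junction 0.15), HG3 (cell cycle -0.12, cholesterol -0.16, tight junction 0.17), HG5 (desmosome 0.19, tight junction 0.16), CON5 or HG2 (cholesterol -0.20 each), and CON1, HG2, HG3 or HG4 (antioxidant -0.09, -0.10, -0.11 and -0.09). Values of called lists also moved by over 1.5 times without HG2 (interferon -0.86), HG5 (cholesterol -0.36, antioxidant -0.21) and CON3 (antioxidant -0.08).

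The second comparison asked how the pelleted high-grain diet differed from the control. MAP2K1 (gene11241), the kinase that activates ERK, was higher in HP, at 75.9 ± 8.4 FPKM against 23 ± 5.12 in CON (SD, n = 5 each; log2 fold change 1.70 ± 0.232 SE, 1.52 relative to the median gene; limma adjusted p 0.0227). CD5L (gene1426) was lower, with 0.0283, 0.459, 0.235, 0.357 and 0.761 FPKM in HP1 to HP5 against 10.1, 5.46, 13, 11 and 40.9 in CON1 to CON5 (log2 fold change -3.36 ± 0.505 SE, -3.54 relative to the median gene; limma adjusted p 0.0448). Interferon-stimulated genes stood below CON in HP: ISG15, a ubiquitin-like antiviral protein, was 23.3 ± 11.2 FPKM against 232.7 ± 108.3, and all 5 HP libraries lay below all 5 CON libraries. By camera with a preset correlation, lists of junctions (0.31), growth factor signalling (0.29) and the basal layer (0.29) stood above CON, and oxidative phosphorylation (-0.52) and ribosomal proteins (-0.59) below it, the latter at -0.22 and -0.21 without CON1 and CON3. With an estimated correlation 0 of 25 lists were called, with a smallest adjusted p of 0.53. In the limma fit 1 gene was higher and 1 lower in HP than CON, with 2954 and 685 at an unadjusted p under 0.05. The latter were 1545 and 1796 under median-ratio scaling and 1485 and 1335 under quantile normalization. With the median-ratio factor as a covariate they were 307 and 343, where chance gives 654 in all, and the smallest limma adjusted p was 0.79. This factor also differed between HP and CON, so a fall to the chance number does not tell scaling from diet.

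**Figure D2:**
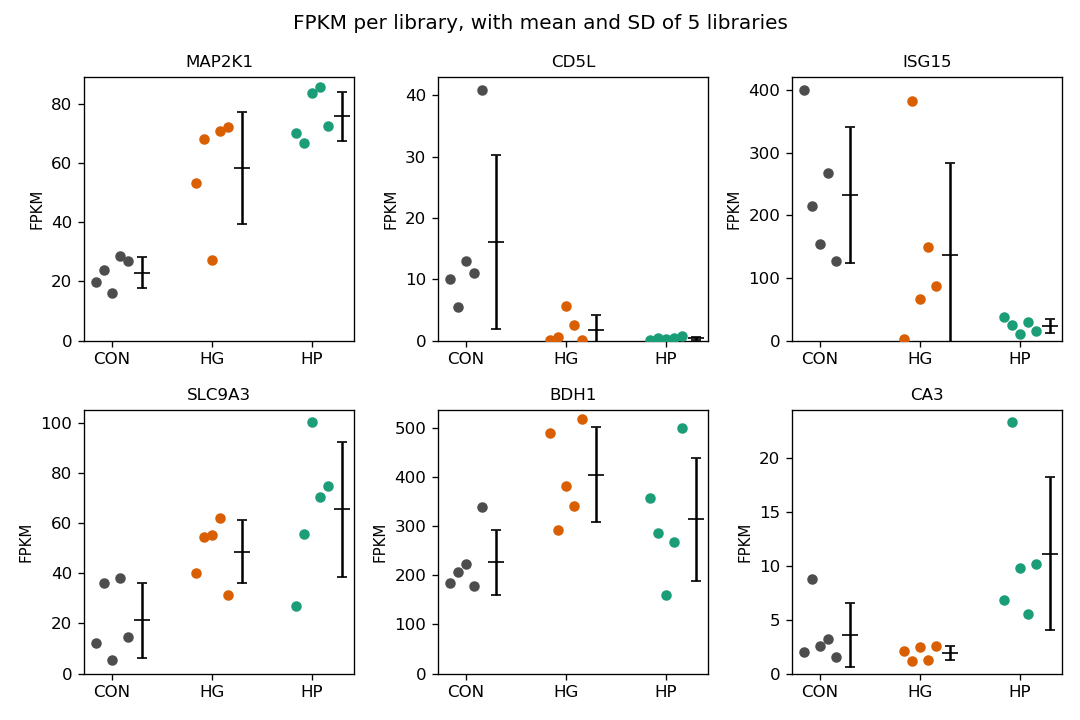
FPKM (y axis) of 6 genes in each library, by group on the x axis; points are libraries, and the bar beside them is the mean with SD of 5 libraries, with the part below 0 not drawn. MAP2K1 is 66.8 to 85.7 in HP and 16.1 to 28.5 in CON, and HG3 at 27.2 lies with CON.

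The genes with the next smallest p in HP against CON were below the threshold. NDUFC1, a complex I subunit, was 2.58 ± 1.28 FPKM in HP against 10.6 ± 4.38 in CON, SYPL1 was 21.4 ± 5.35 against 37.1 ± 4.12, and the methyltransferase cofactor gene TRMT112 was 39.9 ± 6.08 against 84 ± 18.1. Above CON lay SESN3, a stress-induced regulator of growth, with 5.74 ± 1.34 against 2.34 ± 0.719, the kinase gene PASK with 10.1 ± 2.42 against 3.88 ± 1.47, and the centrosomal gene CDK5RAP2 with 6.84 ± 0.631 against 3.66 ± 1.07. TMEM63B was 36.7 ± 4.12 against 20.3 ± 5.65 and QSOX2 17.5 ± 3.09 against 9.69 ± 2.22. Their limma adjusted p was 0.0991.

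Camera with a preset correlation put 4 lists higher and 8 lower in HP than CON. The interferon-stimulated list was lower by -1.12 log2 units relative to all genes (adjusted p 1.2e-13; unadjusted p 0.0807 with an estimated correlation), with 25 of 26 members below CON and 10 lower adjusted over the list alone. In an exact two-sided permutation test of the list score per library its p was 0.00794, the smallest that 5 against 5 libraries can give, and 0.0992 after adjustment over 25 lists. MX1, a GTPase that blocks viruses, was 5.51 ± 2.37 FPKM against 27.6 ± 13.1, IFIT3 0.874 ± 0.621 against 5.42 ± 2.06 and USP18 2.51 ± 0.827 against 12.8 ± 6.18. Innate immunity and inflammation was lower by -0.34 (adjusted p 0.00895; p 0.237 with an estimated correlation; -0.41 and no call with the stricter filter). The chemokine genes were CXCL10 at 1.03 ± 0.369 against 4.05 ± 1.13 and CCL20 at 4.52 ± 3.85 against 11.7 ± 4.41. The myeloid list was lower by -0.40 (adjusted p 0.00225; p 0.247 with an estimated correlation). Its complement genes were C1QA at 30.4 ± 12.9 against 54.7 ± 12.1 and C1QC at 44.5 ± 16.2 against 76.1 ± 16.1. Adjusted over the list alone, 0 members of either list were lower by limma. At an unadjusted p under 0.05, 3 and 3 were lower and 2 and 1 higher in the innate immunity and myeloid lists. In these lists 14 of 32 and 6 of 16 members had a positive fold change. The T and NK cell list stood at -0.26 (adjusted p 0.0535).

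**Figure D3:**
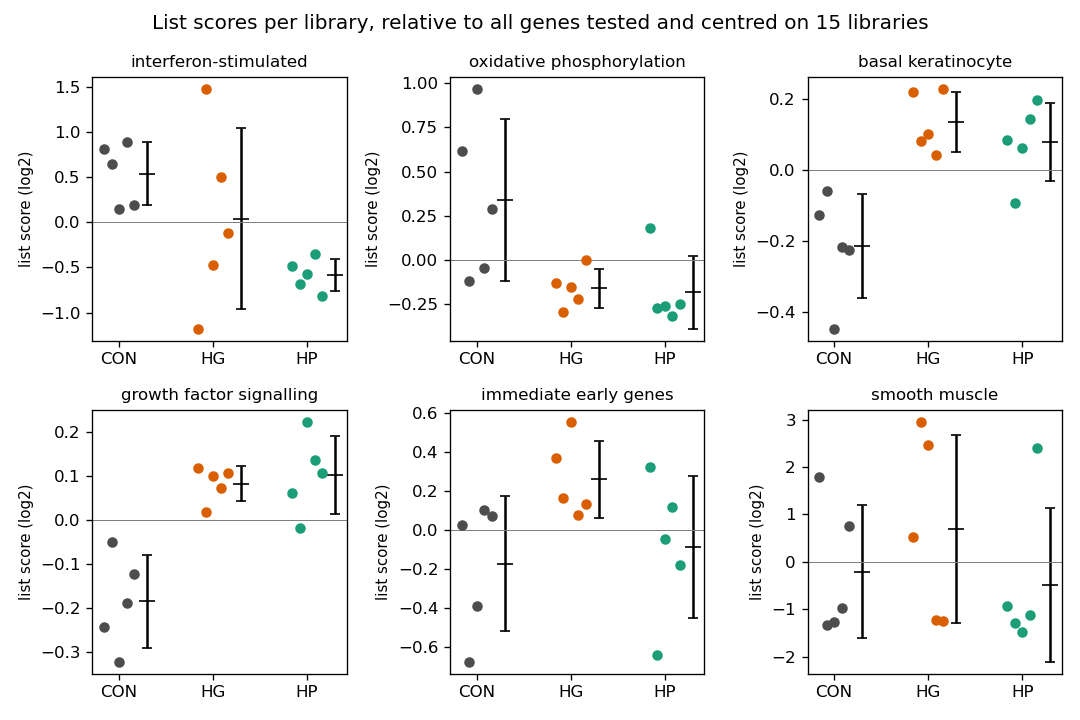
List scores (y axis, mean log2 value of the list minus that of all genes tested, centred on the 15 libraries) by group; points are libraries, and the bar beside them is the mean with SD of 5 libraries. The interferon-stimulated score is -0.81 to -0.35 in HP, 0.14 to 0.89 in CON and -1.18 to 1.48 in HG.

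Desmosome, adherens and gap junction genes were higher by 0.31 (adjusted p 0.003; p 0.245 with an estimated correlation), with 12 of 19 higher adjusted over the list alone. The difference was 0.50 under quantile normalization, 0.19 without CON1 and CON3 and 0.18 with the median-ratio factor as a covariate. Among the 12 were the plakophilin gene PKP1 (157.1 ± 38.2 against 73.2 ± 46.9 FPKM) and CTNND1 (97.8 ± 17.4 against 59.4 ± 22). Growth factor signalling was higher by 0.29 (adjusted p 0.00829; p 0.174 with an estimated correlation), 9 of 28 adjusted over the list alone. ERBB2 was at 26.2 ± 4.91 against 15.4 ± 3.59, NOTCH3 at 23.2 ± 3.08 against 11.9 ± 6.19 and IGF1R at 9.61 ± 2.79 against 4.54 ± 2.87. The basal keratinocyte list was higher by 0.29 (adjusted p 0.0238; p 0.167 with an estimated correlation; 0.33 and no call without CON2 and HP1, 0.19 with the median-ratio factor as a covariate), 2 of 16 adjusted over the list alone, with COL17A1 at 88.9 ± 19.5 against 52.4 ± 16.2. Tight junction genes were higher by 0.19 (adjusted p 0.0413; p 0.371 with an estimated correlation), 1 of 18 adjusted over the list alone. They lost their call under median-ratio scaling (0.16), with the median-ratio factor as a covariate (0.05), with only the 10 libraries (0.19) and without CON1 and CON3 (0.09), and stood at 0.28 without CON2 and HP1. CLDN1 was at 107.8 ± 24.6 against 72.1 ± 20.2. Terminal differentiation genes were not called as a list (0.05, adjusted p 0.952; 0.12 and 0.881 without TGM1, a member listed at 0 in 8 libraries), though 4 of 30 were higher adjusted over the list alone. The envelope gene PPL was 77.4 ± 17.9 against 42.2 ± 12.8 and the transcription factor gene KLF4 70.3 ± 6.41 against 41.2 ± 16.7. SLC9A3 was 65.5 ± 26.9 against 21.2 ± 14.9, PPARA 7.43 ± 0.881 against 3.99 ± 1.25, and the cation channel gene TRPV3 7.12 ± 2.15 against 3.52 ± 1.43.

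Oxidative phosphorylation was lower by -0.52 (adjusted p 1.3e-17; unadjusted p 0.0298, adjusted 0.53, with an estimated correlation), with 32 of 35 members below CON and 13 lower adjusted over the list alone. The difference was -0.18 under quantile normalization, -0.22 without CON1 and CON3 and -0.10 with the median-ratio factor as a covariate. SDHD was 105.8 ± 6.93 FPKM against 148.2 ± 21.1. Cytosolic ribosomal proteins were lower by -0.59 (adjusted p 2e-19; p 0.0578 with an estimated correlation), 7 of 39 adjusted over the list alone. The difference was -0.06 and no call under quantile normalization and with the median-ratio factor as a covariate, -0.21 without CON1 and CON3 and -0.39 without CON3 alone. RPS23 was at 731.7 ± 151 against 1261 ± 408. As in HG, the respiratory and ribosomal genes were highest in CON1 and CON3. Antioxidant genes were lower by -0.20 (adjusted p 0.00618; p 0.0928 with an estimated correlation; 0.02 and no call under quantile normalization, -0.08 and no call without CON1 and CON3). With the median-ratio factor as a covariate they stood at -0.02 with no call. They stood at -0.31 with a pseudocount of 0.1, -0.32 without CON2 and HP1 and -0.17 without SOD1, a member near 0 FPKM in several libraries whose values can be failed estimates. Adjusted over the list alone 0 of 26 were lower by limma, and 6 at an unadjusted p under 0.05. GPX1 was at 672.9 ± 141.5 against 979.9 ± 153.5 and the ferritin gene FTH1 at 774.6 ± 214.1 against 1162 ± 241.5. The unfolded protein and heat shock list was lower by -0.24 (adjusted p 0.00225; p 0.106 with an estimated correlation), a difference of -0.04 and no call under quantile normalization and of -0.13 with the median-ratio factor as a covariate. Ketogenesis was lower by -0.21 (adjusted p 0.0333; p 0.261 with an estimated correlation), which turned to 0.05 under quantile normalization and was -0.06 with no call without CON1 and CON3. It also lost its call with the median-ratio factor as a covariate (-0.001), no filter (-0.16), array quality weights (-0.12), the smooth muscle covariate (-0.21) and without CON2 and HP1 (-0.21). Adjusted over the list alone, 0 members of these lists were lower by limma, with 2 and 2 at an unadjusted p under 0.05, and 7 of 14 ketogenesis members had a positive fold change, 1 at an unadjusted p under 0.05.

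Without CON2, 1840 genes were higher and 331 lower in HP than CON, and without HG1 1 and 2. Without CON1 and CON3, and with array quality weights, 0 were higher and 0 lower by limma, with 830 and 373, and 2744 and 916, at an unadjusted p under 0.05. MAP2K1 missed the threshold without CON1, CON3, CON5 or any single HP library, at log2 fold changes of 1.58 to 1.76, and CD5L without CON1, CON3, CON4, CON5, HG2, HG4 or any single HP library, at -3.46 to -2.96. Lists lost their call without HP1 (basal keratinocyte 0.29, ketogenesis -0.17), CON1, HP3 or HP4 (ketogenesis -0.13, -0.17 and -0.17), and CON2, CON3, HP2, HP3 or HP5 (tight junction 0.21, 0.12, 0.16, 0.13 and 0.18). Without HP5 the myeloid list stood at -0.26 and ketogenesis at -0.33, both still called.

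**Figure D4:**
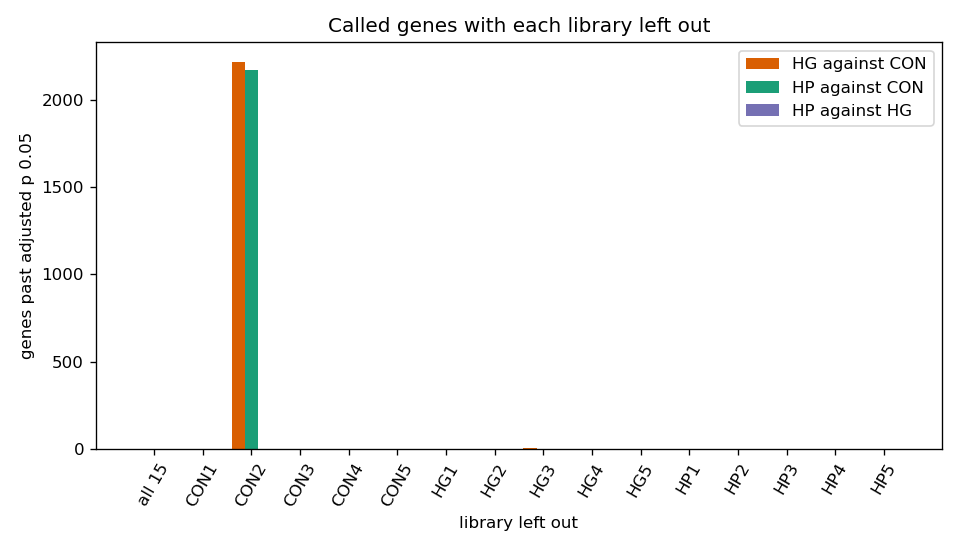
Number of genes past an adjusted p of 0.05 (y axis) in each of the 3 comparisons, with all 15 libraries and with each library left out in turn (x axis). Without CON2 the numbers for higher and lower genes were 1834 and 384 in HG against CON, and 1840 and 331 in HP against CON.

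The third comparison set the pelleted against the non-pelleted high-grain diet. No gene passed the threshold. In the main limma fit, whose spread is shared with CON, fewer genes had an unadjusted p under 0.05 than chance gives. CA3, a carbonic anhydrase, had the smallest p: it was 11.1 ± 7.09 FPKM in HP and 1.9 ± 0.66 in HG (SD, n = 5 each), above every HG library in 5 of 5 HP libraries, with a limma adjusted p of 0.46. By camera with a preset correlation, cholesterol biosynthesis (0.23) and cell cycle genes (0.18) stood above HG as lists, and interferon-stimulated (-0.62), immediate early (-0.34) and smooth muscle genes (-1.17) below it. With an estimated correlation 0 of 25 lists were called, with a smallest adjusted p of 0.78. KRT4, a keratin of stratified epithelium, was 20.3 ± 19.8 against 2.35 ± 1.71 FPKM.

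Of the other genes with the smallest p, PDXK, which makes the active form of vitamin B6, was 9.09 ± 1.15 FPKM in HP against 5.02 ± 0.772 in HG, and the RNA-binding protein gene MATR3 was 67.6 ± 3.15 against 51.8 ± 5.25. The DNA repair gene TDP2 was 4.15 ± 0.473 against 10.1 ± 3.75, EDF1 40.6 ± 9.78 against 69.4 ± 11.9 and the protease gene CAPN2 21.2 ± 2.91 against 30.2 ± 3.47. PAMR1 was 5.78 ± 1.02 against 8.81 ± 1.33, NUDT8 4.01 ± 1.78 against 7.61 ± 1.33 and C1QTNF1 7.7 ± 3.02 against 14.3 ± 5.06.

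By camera, cholesterol biosynthesis was higher in HP than HG by 0.23 relative to all genes (adjusted p 0.000211; p 0.0895 with an estimated correlation). MSMO1 was at 59.5 ± 11 against 40.6 ± 11.7 FPKM and SC5D at 9.38 ± 1.02 against 5.03 ± 3.27. Cell cycle genes were higher by 0.18 (adjusted p 1.7e-05; p 0.236 with an estimated correlation), with 33 of 36 members above HG, and by 0.10 with the smooth muscle covariate. TOP2A was at 8.58 ± 2.67 against 6.28 ± 1.53 and NUSAP1 at 7.09 ± 1.77 against 5.48 ± 1.51. The interferon-stimulated list was lower by -0.62 (adjusted p 1.8e-11; p 0.1 with an estimated correlation), with 26 of 26 members below HG, and by -0.27 without HG2. HG spanned a wide range, and MX1 was 28.3 ± 27.9 in HG against 5.51 ± 2.37 in HP. Immediate early genes were lower by -0.34 (adjusted p 1e-05; p 0.0609 with an estimated correlation), and by -0.21 without HP2. FOS was at 17.4 ± 5.16 against 25.6 ± 5.91 and ATF3 at 1.72 ± 0.554 against 4.59 ± 3.57. Smooth muscle markers were lower by -1.17 (adjusted p 0.00017; p 0.203 with an estimated correlation). Their levels followed single libraries: the marker DES, chosen after its values were seen, was 153.7 to 1579 FPKM in HG1, HG2, HG3 and HP5 and 2.41 to 6.63 in the other libraries of these groups. Adjusted over the list alone, 0 members of any list passed in HP against HG by limma, with 3, 0, 1, 3 and 0 at an unadjusted p under 0.05 in the lists of this paragraph, in the order given.

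Ketogenesis was lower by -0.16 (adjusted p 0.0045; p 0.14 with an estimated correlation), and lost its call with the smooth muscle covariate (-0.09), array quality weights (-0.12), without CON2 and HP1 (-0.12) and under quantile normalization (-0.13). HADH was at 364.4 ± 89 against 457.1 ± 38.6 FPKM and BDH1 at 314.1 ± 125.6 against 404.9 ± 97. Innate immunity (-0.15), the myeloid list (-0.15), endothelium (-0.15) and ribosomal proteins (-0.06) were also called lower, at unadjusted p of 0.25, 0.419, 0.331 and 0.61 with an estimated correlation. All 4 lost their call with no filter (-0.13, -0.13, -0.15 and -0.06, in the order given) and with the stricter filter (-0.16, -0.16, -0.09 and -0.05). Ribosomal proteins also lost it under median-ratio scaling (-0.06), the replicate block (-0.06) and the smooth muscle covariate (-0.06), the myeloid list with only the 10 libraries (-0.15), without CON1 and CON3 (-0.15) and with the median-ratio factor as a covariate (-0.16), and innate immunity without CON2 and HP1 (-0.13). Ribosomal proteins stood at -0.02 with no call with the median-ratio factor as a covariate, -0.02 under quantile normalization, -0.10 with array quality weights and -0.14 without CON2 and HP1, where the myeloid list stood at -0.25. CCL20 was 4.52 ± 3.85 against 10.2 ± 3.87. The unfolded protein and heat shock list was not called (-0.03, adjusted p 0.919), and its member CHAC1 was 0.573 ± 0.42 against 4.39 ± 3.15. In the limma fit 0 genes were higher and 0 lower, with 142 higher and 133 lower at an unadjusted p under 0.05 where chance gives 654, and without HG3 or HP4 1 gene was lower. That fit takes its spread from all groups, of which CON varied most on PC1. With only the 10 libraries compared the unadjusted numbers were 198 and 182, and with array quality weights 341 and 322. The shortfall against chance thus depends on the fit and is not read as a property of the diets. Lists lost their call without HG3 or HP3 (cell cycle 0.08 each), HG2 (smooth muscle -0.61), HG5, HP1, HP3 or HP4 (ketogenesis -0.10 to -0.12), HG4, HP1 or HP5 (innate immunity -0.07, -0.13 and -0.06), CON3, HG2, HG3, HG4, HP2, HP3 or HP5 (myeloid -0.15 to -0.02), HG1, HG2, HG4, HP2, HP3 or HP5 (endothelium -0.13 to -0.06) and CON4, CON5, HG1, HG4, HG5, HP2, HP3 or HP5 (ribosomal -0.07 to 0.05). Called values also moved by over 1.5 times without HG1 (myeloid -0.26), HG3 (smooth muscle -0.73), HG5 (cholesterol 0.37, cell cycle 0.28), HP1 (myeloid -0.25, ribosomal -0.14), HP4 (innate immunity -0.25, myeloid -0.26, endothelium -0.24) and HP5 (ketogenesis -0.28, smooth muscle -1.89).

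Both high-grain groups were compared with the same CON libraries, so their fold changes share chance values. Across genes, which are not independent replicates, the log2 fold changes of HG and HP against CON had a Pearson r of 0.815, where 100 simulated draws of unchanged groups gave 0.469 ± 0.182 (SD). Their covariance was 0.135 against a simulated 0.0368 ± 0.0189, a difference of 0.0978. With CON split into 2 and 3 libraries in 20 ways, r was 0.144 to 0.607, and the covariance was 0.0917 on average. At an unadjusted p under 0.05, 2035 genes were higher and 414 lower in both comparisons. The simulated draws, which share CON in the same way, gave 67.1 and 66.7 on average and at most 971 and 792. As many as observed came in 0 of 100 draws for higher and in 2 of 100 for lower genes. The draws spread the residuals of all 15 libraries over the groups. In the data CON1 and CON3, which stand furthest out, both lie in the shared CON. The SD of PC1 was 38.8 in CON, 7.33 in HG and 14.5 in HP. The draws can therefore understate the r, covariance and overlap that the spread within CON gives, and do not exclude it as a source. The excess of higher over lower genes depends on scaling. Under median-ratio scaling, 1599 genes were higher and 1675 lower in HG against CON at an unadjusted p under 0.05 by limma. In HP against CON they were 1545 and 1796. The overlap was not computed with scaling. No called gene was shared, as HG against CON had 0 by limma.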

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

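Tests chosen only after the result was seen were those of CON2 as an HG sample, of an exchange of CON2 and HP1, of immune cells, and both on smooth muscle. Dixon's ratio was computed for 330 sets of 5 libraries with a limit of 0.71; it singled out 17, and chance alone gives about 1 in 20, or 16.5.

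Single libraries stood apart from their group in these gene values on the log2(FPKM + 1) scale, given with the ratio of gap to range. They were ITPRIP in HP2 (0.795), LZTR1 in HG2 (0.772), LAMA3 in CON3 (0.733), PKP1 in HG4 (0.876), NOTCH3 in HG5 (0.728), SDHD in HP5 (0.777), MSMO1 in HP5 (0.751), COL1A1 in CON3 (0.723), TRPV3 in HG2 (0.721), TDP2 in HG3 (0.792) and PDXK in HG2 (0.779). TGM1, a cross-linking enzyme of the cornified envelope, stood apart in CON3 (0.782) and HP3 (1). It was listed at 0 in CON1, CON4, HG2, HG5, HP1, HP2, HP4 and HP5, at 0.0292 in CON2, 2.11 in CON5 and 0.0132 in HP3, and at 184.1 in CON3, 183.2 in HG1, 188.4 in HG3 and 106.9 in HG4. Values at or near 0 beside such levels can be failed estimates of the quantification, which was not tested, so they are not read as expression of TGM1. Among scores and library measures, HP1 stood apart in oxidative phosphorylation (0.871), HP5 in smooth muscle (0.858), HG5 in endothelium (0.721) and HG1 in the ribosomal share of FPKM (0.88).

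The first pattern is the jump in called genes without CON2 from 0 to 2218 in HG against CON. Scaling between libraries is argued against as the whole source of the number of calls. Without CON2, 1858 genes were called under median-ratio scaling and 1343 under quantile normalization. The share of higher calls went from 82.7% to 48.8% and 54.1%. Only totals were compared, not whether the same genes stayed called. With all 15 libraries, the median-ratio factor as a covariate left 431 higher and 437 lower at an unadjusted p under 0.05 by limma. That fit was not run without CON2, and its covariate differed between the groups, so it cannot separate scaling from diet. Scaling therefore stays open as part of the source. A mislabelled sample stays open: of the 20 genes that best separated HG from CON without CON2, CON2 lay nearer to the other CON libraries in 1, and HG5 lay nearer to its own group in only 8. An exchange of CON2 with HP1 cannot be told apart from other structure, because HP1 lay nearer to the HP mean in 5 of 20 such genes and to the CON mean in 15, where more than 15 had been asked for, and CON2 lay nearer to HP in 20. Against it, HP1 and CON2 lay with the groups of their labels in MAP2K1 (70.4 and 23.98 FPKM), CD5L (0.0283 and 5.46) and the interferon score (-0.49 and 0.65), which were singled out with these labels in place and so exclude nothing. CON2 was picked because the calls rose without it, so the counts of genes by its nearer group largely restate that jump. They are no separate evidence of a mislabelled sample. Differences between lambs within CON stay open and were not tested. The genes used here may follow the axis on which CON1 and CON3 stand apart, which was not tested either.

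The second pattern is the lower interferon-stimulated list in HP. Fewer immune cells may account for part of it: with the T and NK cell and myeloid scores as covariates the difference of HP from CON went from -1.12 ± 0.395 (SE) to -0.58 ± 0.393, which is 51.4% of its size and within 2 SE of 0. Immune cells and a lower response per cell cannot be told apart with 15 libraries. A difference due to diet stays open, as does a different infection or vaccination state of the lambs, which the labels do not give and which was not tested.

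The third pattern is the smooth muscle genes. DES, chosen after its values were seen, was 153.7 to 1579 FPKM in CON1, CON5, HG1, HG2, HG3 and HP5 and 2.41 to 7.3 in the other libraries, and ACTG2 was 96.3 to 1218 against 5.3 to 12.2. Muscle tissue carried along with the epithelium is a candidate source: the other smooth muscle genes followed DES within groups with a median Spearman rho of 0.918. Markers of the same cell type can move together for other reasons, so this does not settle the source. Within groups, the smooth muscle score had a rho of 0.225 with the fibroblast, 0.0536 with the endothelium and 0.129 with the basal keratinocyte score. It was -0.221 with T and NK cells, 0.0286 with oxidative phosphorylation and 0.075 with ribosomal proteins. Diet as the whole source is argued against, since 2 of 5 HG libraries lay above the highest CON library. ACTA2, also made by other contractile cells, followed DES least, with a rho of 0.675.

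Other splits of the 10 libraries of each comparison into 5 and 5 were fitted, 100 drawn for each comparison with the real one among them. For HG against CON the fit of these 10 libraries called 1 gene, 18 of 100 splits gave as many and the highest other gave 6, so chance cannot be excluded. For HP against CON it called 7 genes and 2 of 100 splits, the real one and 1 other, gave as many. The other split, with CON2 and HP1 exchanged, gave 1659, which points to a structure of the samples. The count therefore neither excludes chance nor singles out the grouping by diet. For HP against HG it called 0 genes by limma, 100 of 100 splits gave as many and the highest other gave 3, so chance cannot be excluded.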

How the results depend on the processing

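The settings chosen after seeing the data were those that left out 2 libraries together, the covariates, the lists without TGM1 or SOD1 and the exact test of lists; where no value below shows it, the cause was not tested. Depth is unknown in FPKM, so its limits could not be set. The 112 named gene results kept their direction under the settings run (3011 values), with 28 values losing and 189 gaining the threshold. These genes were picked by small p in the same data, so a kept direction says little. Only MAP2K1 and CD5L in HP against CON were past the threshold in the main fit and could lose it. MAP2K1 kept it in 16 of 27 alternatives and CD5L in 10 of 27. Of 2178 values for 75 list results, 183 lost and 62 gained a call. Direction differed from camera's in the main fit in 143 values of 28 list results. All but the 3 reversed values below were in lists that were not called. For the exact test direction is the sign of the mean, so some of these differ from camera's with the value unchanged. Without single libraries, higher genes ranged from 0 to 1834 and lower from 0 to 384 in HG against CON, from 0 to 1840 and 0 to 331 in HP against CON, and from 0 to 0 and 0 to 1 in HP against HG (lower: 1 without HG3 or HP4). Lists called higher and lower ranged from 3 to 6 and 4 to 9 for HG against CON, 3 to 6 and 7 to 9 for HP against CON, and 1 to 3 and 4 to 8 for HP against HG, and r of the fold changes from 0.752 to 0.866. Lower genes in HP than CON went from 1 to 0 with a pseudocount of 0.1, no filter or the replicate block, and to 6 with only the 10 libraries compared. Higher genes in HG than CON went from 0 to 1 with the stricter filter and with only the 10 libraries. Array quality weights gave 656 higher and 212 lower in HG than CON, and 0 and 0 in HP than CON, where 2744 and 916 had an unadjusted p under 0.05 by limma. Without CON1 and CON3, and with the median-ratio factor as a covariate, HP against CON gave 0 and 0, with 830 and 373, and 307 and 343, at an unadjusted p under 0.05 by limma. For the fit with the covariate chance gives 654 in all, and this covariate cannot be separated from diet. Without CON2 and HP1, 2088 genes were higher and 475 lower in HG than CON and 2485 and 678 in HP than CON, and 3 lists were higher in HG than CON; this pair was picked for its effect on the calls. With the smooth muscle covariate 2 genes were higher in HP than CON and 5 lists lower in HP than HG. Quantile normalization gave 8 lists higher and 3 lower in HG than CON, and 8 and 5 in HP than CON; no filter and the stricter filter each gave 4 lists lower in HP than HG. Estimated correlation in camera and the exact test of scores relative to all genes each called 0 lists in every direction. Reversed were antioxidant genes in HG against CON (0.0674) and ketogenesis in HP against CON (0.0467) under quantile normalization, and ribosomal proteins in HP against HG without HP3 (0.0482; lowest without HP1, -0.144). Terminal differentiation in HG against CON, 0.01 and not called, with camera's direction down, was called higher with the median-ratio covariate (0.34). Replicate numbers did not pair the samples: same-numbered libraries correlated above 0.1 in 0, 2 and 1 of 5 pairs, and the own number was the best partner for 1 of 5 in each comparison.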

Other observations

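The test of the nearer group mean was chosen only after the results were seen. Carbonic anhydrase gene CA3 was 5.49 to 23.3 FPKM in the 5 HP libraries, 1.12 to 2.55 in HG and 1.5 to 8.76 in CON, where CON2 had the highest value. The keratin gene KRT4 was 31.5, 13.6, 4.51, 2.65 and 49.3 in HP1 to HP5, 0.912 to 5.07 in HG and 0.857 to 6.94 in CON. The limma adjusted p of CA3 was 0.0991 and that of KRT4 0.0994 in HP against CON.

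The lists not called in HG or in HP against CON had the values that follow, where the report does not give them. Urea, water and cation channel genes stood at 0.26 in HG and 0.36 in HP against CON (camera adjusted p 0.184 and 0.0604), and 0 and 3 of 9 were higher adjusted over the list alone, with 1 and 4 at an unadjusted p under 0.05 by limma. Transport of short-chain fatty acids, protons and bicarbonate stood at 0.21 in HP against CON (adjusted p 0.312), 3 of 21 adjusted over the list alone. Glycolysis stood at -0.05 and -0.03 (0.871 and 0.936), xenobiotic and retinoid metabolism at -0.09 and 0.04 (0.559 and 0.936), and endothelium at 0.18 and 0.03 (0.103 and 0.782), in HG and HP against CON. Innate immunity stood at -0.19 (0.23), T and NK cells at -0.24 (0.0735), smooth muscle at 0.90 (0.447), the myeloid list at -0.24 (0.0504) and terminal differentiation at 0.01 (0.532), or -0.08 without TGM1 (0.462), in HG against CON. In HP against CON the fibroblast list stood at 0.28 (0.0848), fatty acid oxidation at -0.01 (0.921), smooth muscle at -0.27 (0.233), cholesterol biosynthesis at 0.01 (0.921), cell cycle at -0.04 (0.782) and immediate early genes at 0.09 (0.807).

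In CD5L and MAP2K1 the library HG3 lay with CON, at 5.56 and 27.2 FPKM. By the 20 genes that best separated HG from CON without HG3, it lay nearer to the HG mean in 14. The same count was 20 of 20 for CON3 in its own group. For HG5 it was 8, so that HG5 lay nearer to CON in 12.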
